A study of Mus musculus with 5 samples.

How the data were processed

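RNA was measured in 5 libraries of mouse cochlear organoids, 2 wild-type controls and 3 Jag1 knockouts. Per the labels' protocols, total RNA libraries were made with a stranded kit and sequenced on a NovaSeq as paired reads of 50 bases. The labels name different RNA extraction kits in different places, and do not say whether the controls also received doxycycline. The submitters' processing notes name kallisto and sleuth, without versions. The genome build and transcript index are not given in the sources used here.

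The deposited files give, per the file headers, an estimated count and an effective length for each of 146263 transcripts in each library. Transcript identifiers were matched to GENCODE M21 (GRCm38) without their version, which found 134543 (92.0%), of which 98.2% had the same length there. Matched transcripts held 97.8% to 98.2% of each library's counts. Another 11720 transcripts did not match, 1396 of them with a mean over 50 counts, and were tested apart. Estimated counts were summed to 49028 genes and rounded to whole numbers. TPM, used only in alternatives, was computed from the deposited estimated counts and effective lengths. Coordinates are those of GRCm38.

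Gene counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries scaled with TMM factors, and genotype tested by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Libraries held 42252308 to 51035333 estimated counts. Group means and SDs are of TMM-scaled CPM.

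In all, 31 gene lists were fixed, 6 of them on the biology of the study (Notch components, Notch targets, hair cell, supporting cell, prosensory and Kölliker's organ genes). The others cover cell cycle, stress, metabolism, signalling, matrix, cell types and RNA quality. The 30 lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over lists). Camera called 16 lists, 2 higher and 14 lower. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.26. The rotation test fry was planned beside camera. By fry these camera-called lists did not pass: endoplasmic reticulum stress (adjusted p = 0.0732), G2/M (0.367), Myc (0.0732), FGF and EGF feedback (0.305), epithelial (0.0732) and immediate early (0.0654). The other camera-called lists passed fry in the same direction, with adjusted p from 0.011 to 0.048. So did the matrix list (0.0417, lower), which camera did not call. Random lists matched on mean expression were drawn 10000 times. Lists share members: Jag1 stands in the Notch component and prosensory lists, Sesn2 in the amino acid and p53 lists, Id2 in the Notch target and TGF-beta lists, and Tectb and Gjb2 in the supporting cell and Kölliker's organ lists.

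The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule names Jag1, up to 4 called members of each list with the smallest adjusted p (all members where a list has 5 calls or fewer), and up to 4 uncalled members of the study lists with the highest mean CPM. It also names the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes of at least 5 CPM whose knockout values all lie above or all below both controls. Id1, Mycn, Igf2bp2, Alas2, Krt7, Espn, Otoa, Oc90, Gars, Sars, Iars, Lama1, Igf2, Igfbp4, Fgf3, Fgf15 and Fgf21 were named outside the rule, after their values were seen. Xist and Malat1 are given only as measures of sex and RNA quality. The result of 1 gene the rule names is not reported here.

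The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) with genes of at least 1 TPM in 2 samples, a pseudocount of 0.1, no filter, a filter of 1 CPM, a transcript length offset, protein-coding genes only, no robust fit, the replicate number as a block, each library left out, and a test against a fold of 1.5. A sex term and a fit of the male libraries alone were added after the data were seen. By Xist and Y-linked counts no control was female, so in both the genotype effect rests on knockout 3 against the controls. With 2 against 3 libraries there are 10 splits, so an exact permutation test cannot go below a p of 0.1 and was not used. Where leaving out a library leaves a group with 1, that library is assumed to vary like the other group.

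The test was tested on simulated data with the real means and library sizes of this comparison (22933 genes, 200 of them changed). It recovered 17 of 67 genes changed 1.5-fold, 39 of 67 changed 2-fold and 54 of 66 changed 4-fold, and 15 of its calls (12.0%) were false. Camera called 5 of 5 lowered sets of 20 genes and 0 of 20 unchanged sets, and 4 of the 5 with an estimated correlation. The simulated genes were drawn independently, so these camera counts do not carry over to lists whose members vary together. Among called lists the estimated correlation was highest for endoplasmic reticulum stress (0.66), mitochondrially encoded (0.608), G2/M (0.537) and FGF and EGF feedback genes (0.466). In the other called lists it ran from 0.0148 (hair cell) to 0.332 (immediate early), all above the preset 0.01. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.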

Results

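Cochlear organoids are clusters of cells grown in culture from the sensory epithelium of the inner ear. RNA was sequenced from organoids of postnatal day 2 mouse cochlear cells after 7 days in an expansion medium. The medium held EGF, FGF2, a GSK3 inhibitor, a TGF-beta receptor inhibitor and valproic acid. Doxycycline was added at plating, but the labels do not say whether the controls also received it. The libraries fall into 2 wild-type controls and 3 Jag1 knockouts. Jag1 encodes Jagged1, a ligand of Notch receptors, and the study's title concerns its role in hair cell regeneration. Estimated counts summed to 51035333 and 42764383 in the controls and to 44212742, 42257977 and 42252308 in the knockouts. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Expression values are CPM, counts scaled to a common library size, as mean ± SD (n = 2 controls, n = 3 knockouts, controls first), log2 fold changes are knockout minus control with the SE, and adjusted p-values are from edgeR.

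Jag1 lies on chromosome 2 from 137081456 to 137116644, minus strand (GRCm38, ENSMUSG00000027276.7). It stood at 1581 and 1517 CPM in the controls and at 133, 171 and 145 CPM in the knockouts. The fall from 1549 ± 45.9 to 150 ± 19.3 CPM was 10.4-fold (log2 fold change −3.37 ± 0.12, adjusted p = 2.52e-05). The protein-coding transcript of 26 exons and 5612 bases (ENSMUST00000028735.8) held 70934 and 59896 estimated counts in the controls and 5357, 6638 and 5933 in the knockouts. A transcript of 5 exons annotated as a retained intron (ENSMUST00000133640.2) held 1312 and 1443 counts against 477, 595 and 631. The labels do not name the deleted exons, so the remaining counts were not assigned to exons inside or outside a deletion.

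Of 10 measured genes switched on by Notch signalling, 5 fell. Heyl, a Hairy-related repressor, fell 60.5-fold from 40.2 ± 13.8 to 0.662 ± 0.0789 CPM (−5.92 ± 0.25, adjusted p = 0.000132). Its relatives Hes1 and Hey1 fell from 45.7 ± 3.26 to 10.01 ± 1.31 CPM (−2.19 ± 0.12, adjusted p = 0.000135) and from 94.0 ± 6.73 to 21.8 ± 1.63 CPM (−2.11 ± 0.092, adjusted p = 5.14e-05). Nrarp, a feedback inhibitor of Notch, fell from 22.5 ± 2.24 to 10.6 ± 1.74 CPM (−1.08 ± 0.15, adjusted p = 0.00512), and Id2 from 139 ± 1.22 to 76.4 ± 15.2 CPM (−0.86 ± 0.15, adjusted p = 0.0185). When adjusted over the list alone 7 of the 10 fell, with a list median of −0.97. Camera called the list lower (adjusted p = 3.78e-06; adjusted p = 0.26 with an estimated correlation). Hey2 stood at 47.9 ± 7.65 and 29.3 ± 5.53 CPM (−0.71 ± 0.17, adjusted p = 0.0522), Sox9 at 432 ± 23.4 and 409 ± 53.8 CPM (adjusted p = 0.658), Dtx1 at 21.2 ± 2.77 and 19.6 ± 2.22 CPM (adjusted p = 0.513) and Hes7 at 4.42 ± 0.462 and 5.53 ± 1.17 CPM (adjusted p = 0.321). Id2 did not pass without control 1 (adjusted p = 0.125), control 2 (0.0527) or knockout 3 (0.107).

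Among Notch receptors, ligands and modulators, 3 of 25 measured members fell, Jag1 included. Notch3 fell from 181 ± 1.34 to 113 ± 2.58 CPM (−0.68 ± 0.070, adjusted p = 0.00151) and Notch1 from 817 ± 11.6 to 580 ± 24.3 CPM (−0.49 ± 0.092, adjusted p = 0.0204). When adjusted over the list alone, 2 members were higher and 7 lower. The list median was −0.11, at percentile 30.03 of expression-matched random lists, and camera called the list lower (adjusted p = 0.0347; adjusted p = 0.535 with an estimated correlation). Upper-quartile scaling turned that median to 0.0048. As the list holds Jag1, the targeted gene, and was not tested without it, the call cannot be read as a fall of the other members. The receptor Notch2 stood at 160 ± 0.456 and 136 ± 8.48 CPM (−0.23 ± 0.080, adjusted p = 0.098), Mib1 at 397 ± 21.3 and 339 ± 18.4 CPM (adjusted p = 0.126), Ncstn at 163 ± 18.4 and 132 ± 14.7 CPM (adjusted p = 0.11) and the protease Adam10 at 361 ± 37.9 and 377 ± 72.5 CPM (adjusted p = 0.796). Notch1 did not pass without control 1 (adjusted p = 0.147), control 2 (0.0503) or knockout 2 (0.0897), and a model with the sex of the libraries as a term, added after the data were seen, called 8 members lower.

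**Figure D1:**
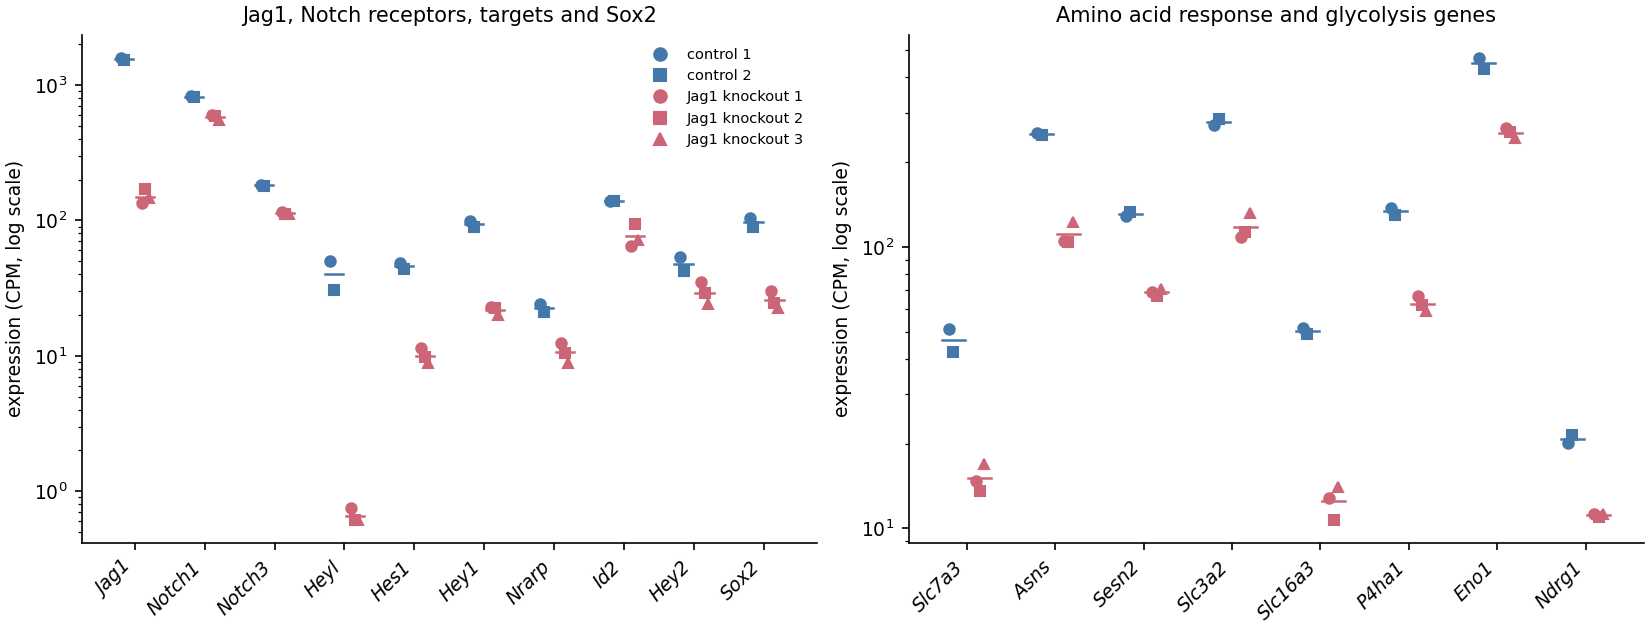
Expression in CPM (log axis) of Jag1, 2 Notch receptors, Notch targets and Sox2 (left) and of amino acid response and glycolysis genes (right). Each marker is a library (2 controls in blue, 3 knockouts in red) and each bar a group mean; Jag1 lies at 1581 and 1517 CPM in the controls and at 133, 171 and 145 CPM in the knockouts, and Hey2 (adjusted p = 0.0522) did not pass the test.

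Sox2, a transcription factor of the prosensory domain that gives rise to hair cells and supporting cells, fell from 96.5 ± 9.52 to 25.6 ± 3.80 CPM (−1.91 ± 0.12, adjusted p = 0.000222). The chromatin protein gene Hmga1 fell from 206 ± 21.4 to 115 ± 1.77 CPM (−0.84 ± 0.083, adjusted p = 0.00131) and the LIM homeobox gene Isl1 from 139 ± 12.8 to 75.2 ± 4.98 CPM (−0.89 ± 0.089, adjusted p = 0.00133). With Jag1, Mycn and Igf2bp2, 6 of 21 measured prosensory and progenitor genes fell, and 10 did when adjusted over the list alone. The list median was −0.31 and camera called it lower (adjusted p = 1.67e-05; adjusted p = 0.26 with an estimated correlation). Jag1, the targeted gene, was among the members tested, and the list was not tested without it. Gata3 stood at 309 ± 6.82 and 235 ± 29.8 CPM (−0.39 ± 0.11, adjusted p = 0.0653), Eya1 at 407 ± 4.88 and 348 ± 2.12 CPM (adjusted p = 0.104) and Eya4 at 281 ± 2.36 and 308 ± 12.7 CPM (adjusted p = 0.269).

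Supporting cells surround hair cells and share progenitors with them. Aqp4, a water channel, fell from 13.3 ± 0.731 to 4.23 ± 0.260 CPM (−1.65 ± 0.14, adjusted p = 0.00065). Otog and Tectb, which encode proteins of the matrices over the sensory epithelia, fell from 734 ± 40.9 to 415 ± 14.96 CPM (−0.82 ± 0.091, adjusted p = 0.00189) and from 116 ± 7.46 to 65.1 ± 9.67 CPM (−0.84 ± 0.12, adjusted p = 0.00633). Cd44 fell from 360 ± 27.6 to 237 ± 5.54 CPM (−0.60 ± 0.083, adjusted p = 0.00575). In all, 8 of 24 measured supporting cell genes fell. When adjusted over the list alone, 2 were higher and 12 lower, and the median was −0.46. Camera called the list lower (adjusted p = 0.000297; adjusted p = 0.26 with an estimated correlation). The stem cell marker Lgr5 stood at 189 ± 1.19 and 191 ± 15.8 CPM (adjusted p = 0.915), Tecta at 6821 ± 754 and 5633 ± 409 CPM (adjusted p = 0.219), Sparcl1 at 1227 ± 238 and 694 ± 158 CPM (−0.82 ± 0.20, adjusted p = 0.0548) and Otogl at 299 ± 48.1 and 312 ± 32.2 CPM (adjusted p = 0.727). Without control 1, 3 members were called lower and Cd44 had an adjusted p of 0.0507; without knockout 2, 5 were called lower, and without knockout 3, 2 were called higher.

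Hair cell genes were mostly weakly expressed, and 2 of 29 measured members rose. Pou4f3, a transcription factor needed for hair cell survival, rose from 0.809 ± 0.0947 to 1.99 ± 0.139 CPM (1.29 ± 0.27, adjusted p = 0.029). Rasd2 rose from 16.5 ± 1.26 to 25.3 ± 1.87 CPM (0.61 ± 0.10, adjusted p = 0.0131). When adjusted over the list alone, 5 members were higher and 1 lower, and the median was 0.61. Camera called the list higher (adjusted p = 0.00111; adjusted p = 0.26 with an estimated correlation). The median lay at percentile 99.2 of 10000 random lists matched on mean expression, whose central 95% lay from 0.0095 to 0.55. Myo6 stood at 130 ± 15.9 and 120 ± 17.0 CPM (adjusted p = 0.54), Jag2 at 58.6 ± 1.004 and 67.6 ± 1.25 CPM (adjusted p = 0.103), Pcdh15 at 36.0 ± 6.28 and 40.1 ± 5.96 CPM (adjusted p = 0.471) and Hes6 at 24.0 ± 2.52 and 26.0 ± 1.89 CPM (adjusted p = 0.455). Neither gene passed without control 1 (Rasd2 adjusted p = 0.126, Pou4f3 0.118), and Pou4f3 also did not pass without control 2 (0.0662), knockout 1 (0.0593) or knockout 2 (0.105). With the sex term, 4 members were called higher and 2 lower.

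Kölliker's organ is the epithelium beside the sensory cells in the immature cochlea. Fgf10, a growth factor made there, fell from 347 ± 39.9 to 151 ± 3.49 CPM (−1.20 ± 0.089, adjusted p = 0.000429). Ano1, a calcium-activated chloride channel, fell from 81.9 ± 3.02 to 33.5 ± 6.18 CPM (−1.29 ± 0.13, adjusted p = 0.00186), and the gap junction gene Gjb2 from 398 ± 32.8 to 297 ± 26.2 CPM (−0.42 ± 0.10, adjusted p = 0.0495). With Tectb, 4 of 15 measured members fell, and when adjusted over the list alone 3 were higher and 6 lower. The median was −0.027, which upper-quartile scaling turned to 0.084, and camera did not call the list (adjusted p = 0.141). With the sex term, camera did call it lower. Epyc stood at 832 ± 29.8 and 898 ± 59.6 CPM (adjusted p = 0.465), Clu at 996 ± 96.7 and 749 ± 33.1 CPM (adjusted p = 0.055) and Dcn at 626 ± 92.7 and 617 ± 85.1 CPM (adjusted p = 0.923). Gjb2 did not pass without control 1 (adjusted p = 0.332), knockout 1 (0.0535) or knockout 2 (0.114).

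Across the transcriptome, 1372 of 23415 tested genes passed an adjusted p of 0.05, 339 higher and 1033 lower in the knockouts. Among the 10 protein-coding genes with the largest rises were Smoc2, a secreted calcium-binding protein gene, from 20.1 ± 2.95 to 177 ± 45.1 CPM (3.14 ± 0.27, adjusted p = 0.00416), and the tendon transcription factor gene Scx, from 5.21 ± 1.203 to 22.8 ± 3.21 CPM (2.14 ± 0.18, adjusted p = 0.000573). The metallothionein gene Mt1 rose from 56.5 ± 6.68 to 134 ± 4.90 CPM (1.24 ± 0.094, adjusted p = 0.000467), and the metalloproteinase genes Adamts16 and Adamts18 rose with log2 fold changes of 1.18 ± 0.11 and 1.17 ± 0.092. The other large rises, in Wscd2, Fam220a, Rasgef1b, mt-Atp6 and Fam196a, ran from 1.17 to 1.33. Beside Heyl, Jag1, Hes1 and Hey1, the 10 largest falls held Sorcs1 (−2.86 ± 0.23), Dpysl4 (−2.85 ± 0.27), Igfbp3 (−2.79 ± 0.22), Cavin3 (−2.66 ± 0.14), Rtp1 (−2.27 ± 0.23) and Igfbpl1 (−2.21 ± 0.13). Igfbp3, an insulin-like growth factor binding protein gene, fell from 35.6 ± 8.32 to 5.14 ± 1.204 CPM (adjusted p = 0.00131), and Cavin3, a component of caveolae, from 54.0 ± 9.46 to 8.56 ± 1.23 CPM (adjusted p = 0.000135). Smoc2 did not pass without control 1 (adjusted p = 0.0753) or knockout 3 (0.077), nor Fam196a without control 1 (0.0854), nor mt-Atp6 without knockout 3 (0.0813).

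The lower genes were mostly protein-coding (992 of 1033, 96.0%) with a median of 52.8 CPM, and the higher genes less so (184 of 339, 54.3%) with a median of 7.89 CPM. At least a 2-fold change was seen in 152 higher and 193 lower genes. In all 1372 the 3 knockout libraries lay together above or together below both controls, as they did in 53.6% of all tested genes. The average over the 10 possible splits is 20%. Genes vary together, so a single split can lie far from that average without an effect of genotype. The split of calls depended on the scaling: 24.7% were higher with TMM factors and 39.8% (458 higher, 694 lower) with upper-quartile factors, which moved the median log2 fold change of all genes from 0.044 to 0.16. Calls numbered 408 without control 1 and 504 without knockout 2, and 3484 with DESeq2. They numbered 177 with limma-trend on log2(TPM + 1), which called 26 of the 73 named genes it measured that had passed. A model with a sex term, chosen after seeing the data, called 5063 genes. As no control was female, its genotype effect rests on knockout 3 against the controls. Each of the 1372 genes had the same sign with the sex term. That was bound to be so, since knockout 3 lay beyond both controls in all of them. Other counts of fixed lists that the sex term moved by over 1.5 times were 8 lower Notch components, 4 lower G2/M genes, 7 lower Myc and ribosome biogenesis genes, 5 lower FGF and EGF feedback genes, 6 lower epithelial genes, 4 lower immediate early genes, 3 higher matrix genes, 2 higher Wnt targets, and 1 gene each in the prosensory (higher), cholesterol (lower), Schwann cell (lower) and red blood cell (higher) lists.

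Genes of the amino acid response driven by the transcription factor ATF4 formed a fixed list. The amino acid transporter genes Slc7a3 and Slc3a2 fell from 46.7 ± 5.9995 to 15.04 ± 1.71 CPM (−1.63 ± 0.12, adjusted p = 0.000419) and from 278 ± 10.6 to 118 ± 12.5 CPM (−1.24 ± 0.096, adjusted p = 0.000476). Asns, which makes asparagine, fell from 251 ± 3.44 to 111 ± 10.6 CPM (−1.18 ± 0.091, adjusted p = 0.00047), and Sesn2, a sensor that restrains mTORC1, from 131 ± 2.84 to 69.0 ± 1.92 CPM (−0.92 ± 0.071, adjusted p = 0.00047). In all, 20 of 24 measured members fell, and 23 did when adjusted over the list alone, with a median of −0.94. Camera called the list lower (adjusted p = 2.05e-23; adjusted p = 0.26 with an estimated correlation). Without any single library, 17 to 21 members were called lower.

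Glycolysis and hypoxia genes formed another list. The lactate exporter gene Slc16a3 fell from 50.1 ± 1.72 to 12.5 ± 1.66 CPM (−2.00 ± 0.11, adjusted p = 0.000135) and the collagen prolyl hydroxylase gene P4ha1 from 134 ± 4.89 to 62.7 ± 3.95 CPM (−1.09 ± 0.080, adjusted p = 0.000429). The glycolytic enzyme gene Eno1 fell from 450 ± 27.8 to 254 ± 10.6 CPM (−0.82 ± 0.086, adjusted p = 0.00151) and Ndrg1 from 20.8 ± 1.02 to 11.1 ± 0.136 CPM (−0.90 ± 0.10, adjusted p = 0.0019). Of 24 measured members 16 fell, and 21 did when adjusted over the list alone, with a median of −0.74. Camera called the list lower (adjusted p = 7.56e-16; adjusted p = 0.26 with an estimated correlation).

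Of 15 endoplasmic reticulum stress genes, Herpud1 fell from 69.3 ± 1.71 to 33.3 ± 2.20 CPM (−1.06 ± 0.083, adjusted p = 0.000489) and Dnajb9 from 30.6 ± 4.11 to 22.3 ± 1.75 CPM (−0.46 ± 0.11, adjusted p = 0.0472), and 10 were lower when adjusted over the list alone. That list's median was −0.36 and camera called it lower (adjusted p = 1.87e-06; adjusted p = 0.425 with an estimated correlation). Dnajb9 passed only in the leave-out without control 2, with adjusted p-values of 0.368 without control 1 and of 0.0532, 0.105 and 0.0546 without knockouts 1, 2 and 3. The list held 1 call without control 1, 6 without control 2 and 12 with the sex term. Of 21 p53 targets 4 fell, and 10 did when adjusted over the list alone, with a median of −0.19 at percentile 5.3 of expression-matched lists and a camera call (adjusted p = 3.12e-05; adjusted p = 0.26 with an estimated correlation). They were Sesn2, Gdf15 from 7.10 ± 0.457 to 2.34 ± 0.212 CPM (−1.60 ± 0.19, adjusted p = 0.00262), Cdkn1a from 124 ± 6.42 to 91.4 ± 2.89 CPM (−0.44 ± 0.075, adjusted p = 0.0149) and Ccng1 from 191 ± 4.75 to 146 ± 12.7 CPM (−0.39 ± 0.090, adjusted p = 0.0427). Cdkn1a did not pass without control 2 (0.0522) or knockout 2 (0.0518), nor Ccng1 without control 1 (0.242), control 2 (0.0607), knockout 1 (0.0533) or knockout 2 (0.0907). The p53 list held 2 calls without control 2 or knockout 2 and 9 with the sex term.

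Cell cycle genes themselves did not pass. By edgeR 0 of 25 G2/M genes were called, also when adjusted over the list alone, with 3 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Camera called the G2/M list lower (adjusted p = 0.00995; adjusted p = 0.766 with an estimated correlation), but its median of −0.13 lay at percentile 54.6 of expression-matched random lists. Of 25 S phase genes 0 were called, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.343). The S phase median of 0.069 lay at percentile 100 of expression-matched lists, whose central 95% lay from −0.21 to −0.036. Of 7 cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn1b fell, the latter from 193 ± 2.58 to 137 ± 17.7 CPM (−0.50 ± 0.11, adjusted p = 0.0325). When adjusted over the list alone 1 was higher and 2 lower, with a median of −0.27 that camera did not call (adjusted p = 0.118). Cdkn1b did not pass without control 1 (0.121), control 2 (0.0547) or knockout 2 (0.101). The Myc and ribosome biogenesis list held 2 lower genes of 21, as it did when adjusted over the list alone. They were Srm, from 56.6 ± 1.11 to 40.4 ± 2.85 CPM (−0.49 ± 0.085, adjusted p = 0.0161), and Odc1, from 217 ± 14.1 to 154 ± 13.5 CPM (−0.50 ± 0.093, adjusted p = 0.0207). Both encode polyamine synthesis enzymes, and neither passed without control 1 (Srm 0.101, Odc1 0.151). The list median was −0.18, at percentile 19.5 of expression-matched lists (camera adjusted p = 0.000966; adjusted p = 0.506 with an estimated correlation). Of 22 cholesterol synthesis genes 0 were called by edgeR, DESeq2 or limma-voom, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05. The median was −0.062 (0.049 with upper-quartile scaling, camera adjusted p = 0.506). With the sex term, camera called the cholesterol list lower.

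Signalling lists were tested for the pathways the medium acts on. Lef1, a nuclear partner of beta-catenin, rose from 49.3 ± 6.42 to 87.6 ± 12.98 CPM (0.83 ± 0.14, adjusted p = 0.0143). The secreted Wnt inhibitor gene Wif1 fell from 24.7 ± 0.763 to 14.9 ± 1.53 CPM (−0.73 ± 0.11, adjusted p = 0.00757), and Tnfrsf19 from 503 ± 56.5 to 335 ± 32.9 CPM (−0.59 ± 0.11, adjusted p = 0.0226). These were the calls among 14 Wnt targets, with 1 higher and 3 lower when adjusted over the list alone. The median of −0.019 turned to 0.092 with upper-quartile scaling, and camera did not call the list (adjusted p = 0.595). Lef1 did not pass without knockout 3 (0.0677), nor Tnfrsf19 without control 2 (0.0617). Of 22 TGF-beta and BMP pathway genes 6 fell, Id1 and Id2 among them, and 9 did when adjusted over the list alone, with a median of −0.31. Camera called the list lower (adjusted p = 0.000162; adjusted p = 0.293 with an estimated correlation). Bambi, a decoy receptor, fell from 28.2 ± 1.44 to 11.6 ± 1.95 CPM (−1.27 ± 0.13, adjusted p = 0.00166), and Fstl3, an activin antagonist gene, from 3.35 ± 0.402 to 0.916 ± 0.127 CPM (−1.87 ± 0.25, adjusted p = 0.00492). The matrix-associated gene Ccn2 fell from 64.1 ± 19.7 to 19.2 ± 3.01 CPM (adjusted p = 0.0105), and the activin subunit gene Inhba from 66.0 ± 8.27 to 41.8 ± 3.97 CPM (adjusted p = 0.0121). Ccn2 did not pass without knockout 3 (0.117), where 3 members were called lower, nor Inhba without knockout 2 (0.053).

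Among 17 FGF and EGF feedback genes, Spry4 fell from 83.5 ± 4.15 to 49.0 ± 6.05 CPM (−0.77 ± 0.11, adjusted p = 0.00542) and Spry2 from 139 ± 11.1 to 100.2 ± 10.8 CPM (−0.47 ± 0.10, adjusted p = 0.0343), and 4 were lower when adjusted over the list alone. The median was −0.14, at percentile 36.8 of expression-matched lists (camera adjusted p = 0.0382; adjusted p = 0.766 with an estimated correlation). Spry2 did not pass without control 1 (0.229) or knockout 2 (0.111). Among 16 interferon response genes Bst2 fell from 18.6 ± 4.58 to 10.4 ± 1.22 CPM (−0.83 ± 0.17, adjusted p = 0.0265), the 1 call also when adjusted over the list alone. It did not pass without control 1 (0.22) or knockout 2 (0.0705). The list's median was 0.11 and its mean 0.063 while camera pointed down (adjusted p = 0.89).

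Matrix genes went both ways. The basement membrane collagen genes Col4a1 and Col4a2 fell from 176 ± 3.85 to 75.3 ± 9.04 CPM (−1.22 ± 0.10, adjusted p = 0.000573) and from 183 ± 10.2 to 78.3 ± 12.3 CPM (−1.22 ± 0.12, adjusted p = 0.00131). Fibronectin (Fn1) fell from 600.3 ± 37.8 to 348 ± 21.9 CPM (−0.79 ± 0.095, adjusted p = 0.00289) and its receptor subunit gene Itga5 from 21.3 ± 2.83 to 12.96 ± 1.06 CPM (−0.72 ± 0.12, adjusted p = 0.0143). Tenascin C (Tnc) rose from 23.4 ± 0.224 to 34.6 ± 3.30 CPM (0.57 ± 0.099, adjusted p = 0.0158). These were the calls among 16 extracellular matrix and mesenchymal transition genes, with 3 higher and 4 lower when adjusted over the list alone. The median was 0.24 and the mean 0.11 while camera pointed down (adjusted p = 0.711). Neither Itga5 (0.132) nor Tnc (0.0897) passed without control 1. Among keratin genes, 3 fell: Krt18 from 80.9 ± 7.07 to 40.4 ± 5.42 CPM (−1.003 ± 0.11, adjusted p = 0.00231), Krt8 from 122 ± 14.995 to 61.6 ± 8.55 CPM (−0.99 ± 0.12, adjusted p = 0.00358) and Krt19 from 9.56 ± 1.51 to 3.84 ± 0.309 CPM (−1.32 ± 0.18, adjusted p = 0.00492). Krt7 stood at 3.92 ± 1.52 and 5.87 ± 1.46 CPM (0.59 ± 0.29, adjusted p = 0.197). The 3 keratins were the calls among 15 epithelial genes, of which 6 were lower when adjusted over the list alone. That median was −0.21, at percentile 9.16 of expression-matched lists (camera adjusted p = 0.00415; adjusted p = 0.425 with an estimated correlation).

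Markers of other cell types that a cochlear preparation can hold gave few calls. Of 14 mesenchyme and fibrocyte markers the pericyte gene Pdgfrb fell from 6.21 ± 2.75 to 1.15 ± 0.341 CPM (−2.43 ± 0.34, adjusted p = 0.00633), the 1 call also when adjusted over the list alone (median 0.082, camera adjusted p = 0.901). By edgeR 0 members passed among 9 Schwann cell and glia markers, 11 neuron markers, 5 immune cell markers, 7 endothelial markers, 7 melanocyte and strial markers and 8 markers of Reissner's membrane, roof and outer sulcus. At an unadjusted p under 0.05 these lists held 2, 3, 1, 1, 3 and 4 members, DESeq2 called 0, 0, 0, 1, 1 and 3, and limma-voom 0 in each. When adjusted over the list alone, 1 melanocyte marker was higher, 3 members of the Reissner's membrane list were higher and 1 lower, and 0 members of the other 4 lists passed. Camera adjusted p-values were 0.901 (Schwann cell, median −0.030, mean 0.12, 0.081 as the upper-quartile median), 0.786 (neuron, median 0.10, mean −0.099), 0.105 (immune, median 0.46), 0.639 (endothelial, median 0.35), 0.595 (melanocyte, median 0.31) and 0.548 (Reissner's membrane, median 0.30, mean −0.44). Camera pointed down for the Schwann cell and neuron lists and up for the others. Of 7 red blood cell markers 1 was measured, Alas2 (log2 fold change 1.01), so adjusting over the list alone left its p unchanged. Alas2 passed at that unadjusted p and with DESeq2, but not over all genes in edgeR or limma-voom.

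**Figure D2:**
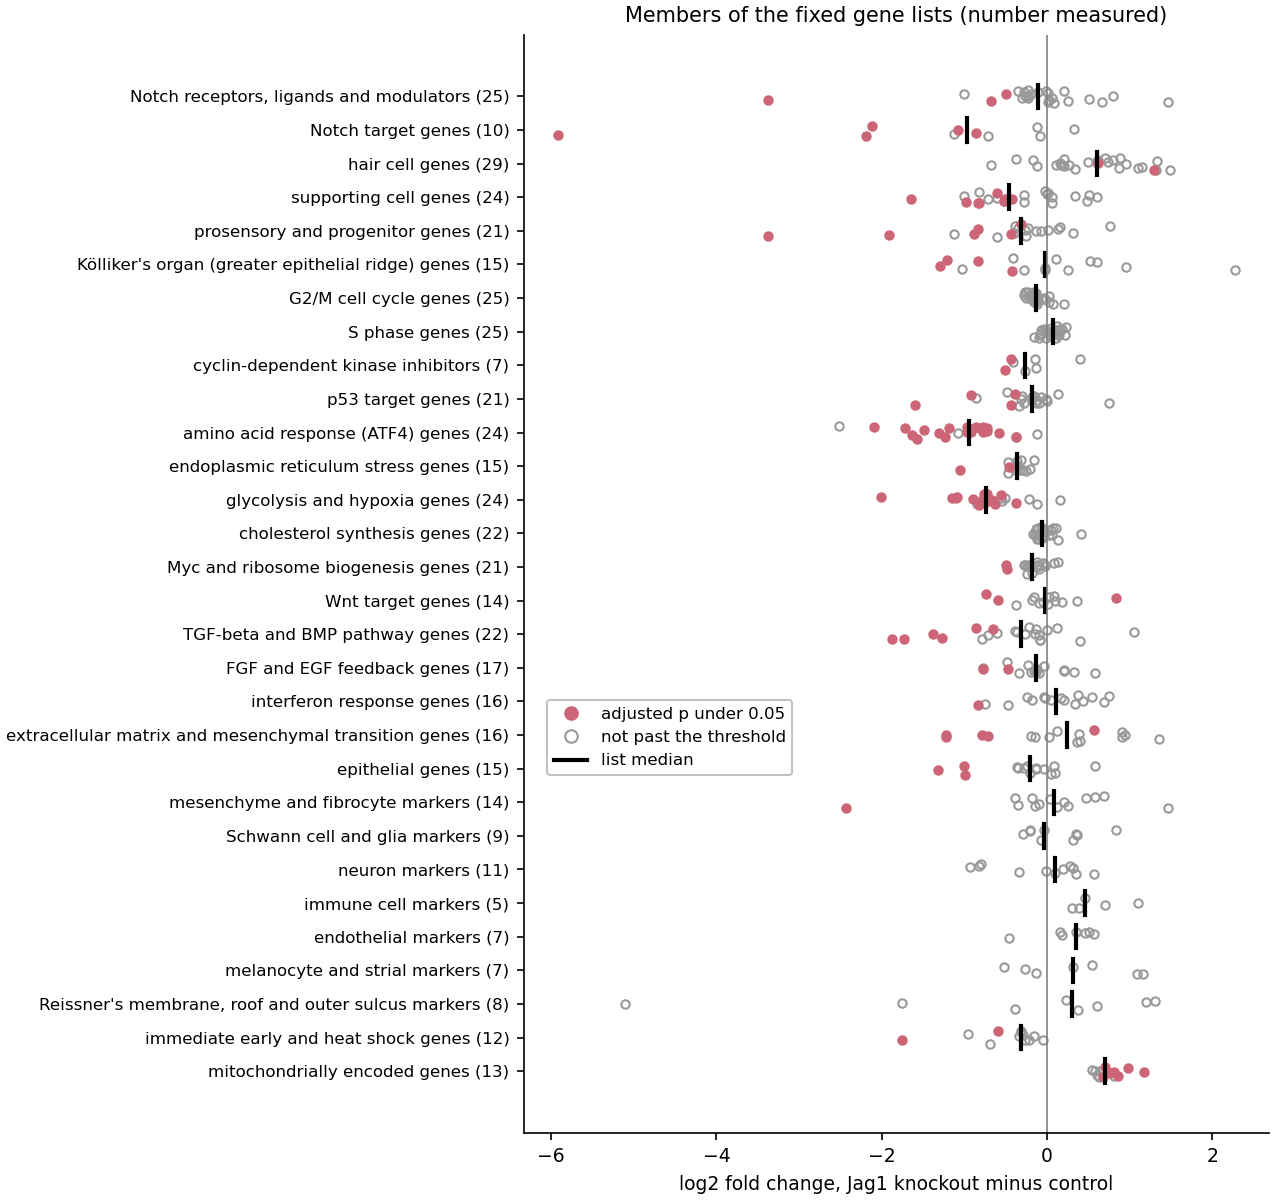
Log2 fold change (knockout minus control, horizontal axis) of each measured member of 30 fixed gene lists, with the number measured in brackets, filled where the adjusted p was under 0.05, and with a bar at the list median. The amino acid response (median −0.94), Notch target (−0.97) and glycolysis (−0.74) lists lie left of 0, and hair cell (0.61) and mitochondrially encoded genes (0.70) right of it.

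Of 13 mitochondrially encoded genes 7 rose, and 12 did when adjusted over the list alone, with a median of 0.70 and a camera call (adjusted p = 1.4e-08; adjusted p = 0.374 with an estimated correlation). mt-Cytb rose from 825 ± 116 to 1447 ± 53.3 CPM (0.81 ± 0.12, adjusted p = 0.00841), mt-Atp6 from 218 ± 64.8 to 493 ± 16.1 CPM (adjusted p = 0.00865), mt-Nd4 from 429 ± 89.0 to 781 ± 53.7 CPM (adjusted p = 0.0114) and mt-Nd5 from 451 ± 89.5 to 765 ± 45.3 CPM (adjusted p = 0.0162). Without control 1, 3 members passed, and mt-Cytb (0.0806), mt-Nd4 (0.0664) and mt-Nd5 (0.116) did not. mt-Nd5 did not pass without knockout 2 (0.0556), nor mt-Atp6 without knockout 3 (0.0813), and without control 2 11 members passed. Of 12 immediate early and heat shock genes, which respond to handling, 2 fell, and 4 did when adjusted over the list alone, with a median of −0.32 and a camera call (adjusted p = 0.00039; adjusted p = 0.425 with an estimated correlation). Atf3 fell from 1.72 ± 0.197 to 0.508 ± 0.0995 CPM (adjusted p = 0.0143) and Hspa1b from 15.3 ± 0.787 to 10.1 ± 1.203 CPM (adjusted p = 0.0376). Neither passed without control 1 (Atf3 0.0733, Hspa1b 0.241) or knockout 2 (0.0738 and 0.104), nor Hspa1b without control 2 (0.0522).

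The first principal component of log2 CPM held 54.7% of the variance and separated the libraries by genotype, with scores of −75.7 and −23.1 in the controls and 11.3, 26.4 and 61.3 in the knockouts. Mitochondrially encoded mRNA took 0.573% and 0.769% of counts in the controls and 1.12%, 1.27% and 1.32% in the knockouts. Ribosomal protein genes took 3.24% and 3.09% against 2.83%, 2.61% and 2.57%. The nuclear RNA Malat1 took 0.309% and 0.4998% against 0.497%, 0.527% and 0.823%. Olfactory and vomeronasal receptor genes, which this tissue is not known to use, summed to 1780 and 2480 CPM against 2840, 3080 and 4090 CPM. Xist, the X-inactivation RNA of female cells, had 84 and 80 counts in the controls and 106055, 110562 and 187 in the knockouts, and 4 Y-linked genes had 9274 and 9095 counts against 595, 612 and 10384. Both controls and knockout 3 were thus male by these genes and knockouts 1 and 2 mostly female.

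**Figure D3:**
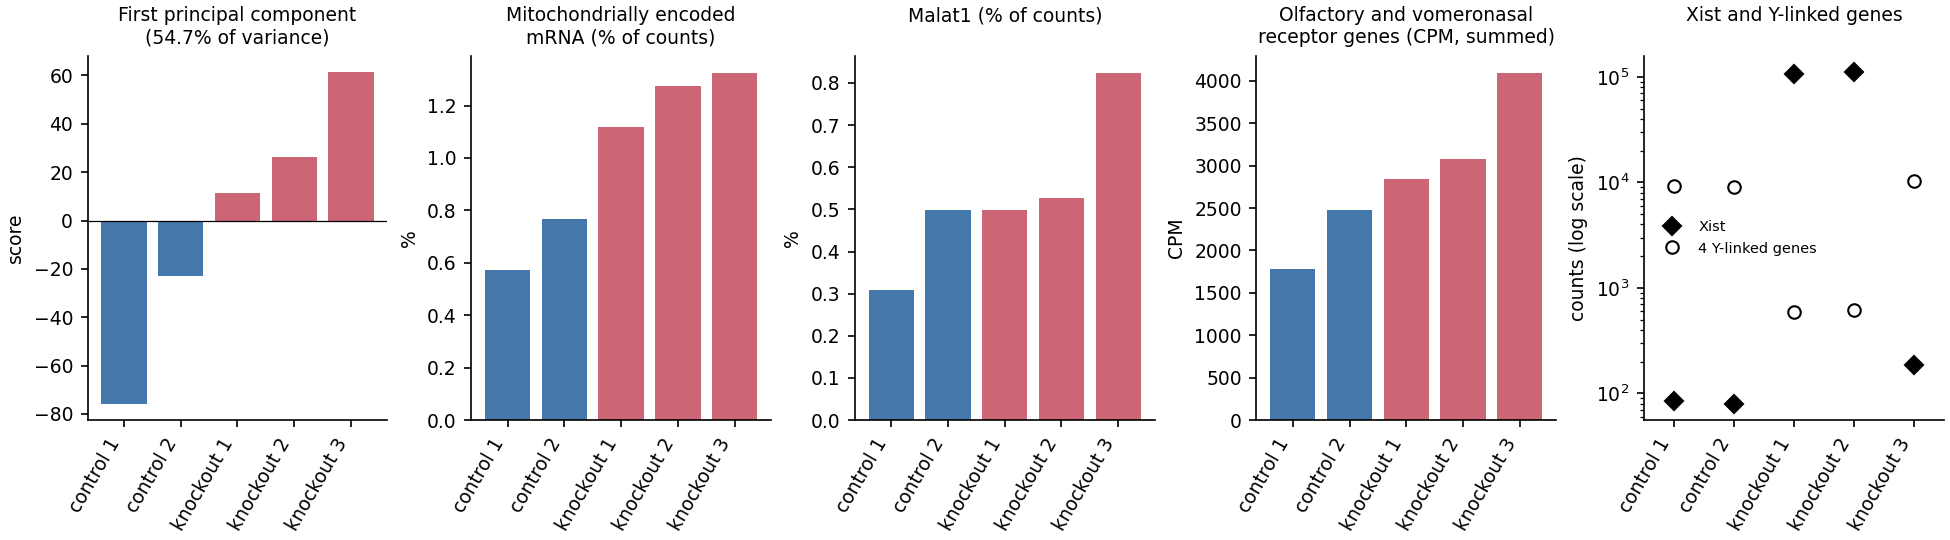
Values per library for the 2 controls (blue) and 3 knockouts (red): first principal component score, percent of counts in mitochondrially encoded mRNA and in Malat1, summed CPM of olfactory and vomeronasal receptor genes, and counts of Xist and 4 Y-linked genes (log axis). Xist counts are 106055 and 110562 in knockouts 1 and 2 and 80 to 187 in the other libraries.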

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

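The sex term and the fit of male libraries alone were chosen after seeing the data. Jag1 was lower in every alternative run (−3.47 to −2.97). None of the 75 other named genes that passed changed direction in any alternative run. For the leave-outs and the fits for sex this says little, since every called gene had all knockouts beyond both controls. As for passing, limma-trend on log2(TPM + 1) kept 26 of 73 and the test against a 1.5-fold change kept 31 of 75. Leaving out control 1 lost 22 of the 75, control 2 lost 8, and knockouts 1, 2 and 3 lost 4, 13 and 6. The cause of these losses was not tested, beyond the smaller number of samples. No alternative varied the depth, so what depth limits was not tested.

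The count of 1372 changed genes (339 higher, 1033 lower) became 3484 with DESeq2 (1242 and 2242) and 2167 without the low-count filter (733 and 1434). It became 177 with log2(TPM + 1) (78 and 99), 202 with a pseudocount of 0.1 (103 and 99), 37 with TPM and no filter (10 and 27), and 97 against a 1.5-fold change (15 and 82), a test built to call fewer genes. With limma-voom 192 genes were higher, and with upper-quartile factors 694 were lower. The sex term gave 5063 (2074 and 2989) and the male libraries alone 4305 (1849 and 2456). Over the leave-outs the count ran from 408 to 1781, the higher genes from 63 to 863 and the lower from 345 to 995. Camera called 14 to 17 lists in the leave-outs and 0 with an estimated correlation, against 16. In the male libraries alone the lists held 13 lower endoplasmic reticulum stress genes, 5 lower Notch components, 6 lower epithelial genes and 12 higher mitochondrially encoded genes. The cause was not tested except where stated.

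Samples of the same number were not shown to be paired. Their deviations correlated at 0.389 (control 1 and knockout 1) and −0.117 (control 2 and knockout 2). The replicate block, which leaves knockout 3 unpaired, called 4051 genes (1649 higher, 2402 lower) and turned the log2 fold change of uncalled Sox9 to 0.026, Myo6 to 0.0019 and Dcn to 0.097.

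Named genes that did not pass changed sign as follows, and the cause was not tested. Sox9 (−0.079) was 0.029 with upper-quartile factors and 0.028 with each TPM setting. Dcn (−0.021) was 0.089 with upper-quartile factors, 0.10 with each TPM setting, 0.025 with the stricter filter and 0.052 with protein-coding genes only. Dtx1 (−0.12) was 0.086 with log2(TPM + 1), filtered or not, and 0.095 with a pseudocount of 0.1. Myo6 (−0.11) was 0.097 and 0.099 in the same settings. Lgr5 (0.015) was −0.013 with RLE factors and −0.031 with DESeq2. With the sex term and in the male libraries alone, Adam10 (0.061) was −0.10 and −0.099, Pcdh15 (0.15) −0.038 and −0.035, Hes6 (0.11) −0.010 and −0.0074, and Otogl (0.065) −0.092 and −0.090. Over the leave-outs the ranges were −0.10 to 0.17 for Adam10, −0.14 to 0.030 for Sox9, −0.25 to 0.017 for Dtx1, −0.24 to 0.013 for Myo6, −0.017 to 0.34 for Pcdh15, −0.094 to 0.24 for Otogl, −0.035 to 0.0805 for Lgr5 and −0.17 to 0.13 for Dcn.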

Other observations

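Gene groups chosen after seeing the values showed further falls. Of 20 measured aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, 13 fell, with a median log2 fold change of −0.53 (camera adjusted p = 6.37e-14; adjusted p = 0.0477 with an estimated correlation). Gars fell from 248 ± 1.59 to 149 ± 5.55 CPM (mean ± SD, adjusted p = 0.00131), Sars from 223 ± 3.14 to 135 ± 4.05 CPM (0.00129) and Iars from 317 ± 9.08 to 188 ± 7.75 CPM (0.00146). Ribosomal protein genes fell in 26 of 81 cases, with a median of −0.38 (camera adjusted p = 3.63e-23; adjusted p = 0.31 with an estimated correlation), and in 63 with the sex term.

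Of 21 basement membrane collagen and laminin genes, also picked after the fact, 8 fell (camera adjusted p = 6.06e-07; adjusted p = 0.0574 with an estimated correlation), with Lama1 from 115 ± 18.1 to 38.3 ± 3.34 CPM (log2 fold change −1.59 ± 0.11, adjusted p = 0.000372). Among 8 insulin-like growth factor ligand and binding protein genes Igf2 (−0.83 ± 0.10), Igfbp3, Igfbp4 (−0.43 ± 0.098) and Igfbpl1 fell (camera adjusted p = 6.78e-05; adjusted p = 0.0574 with an estimated correlation). Among 22 fibroblast growth factor genes Fgf3 (−2.16 ± 0.33), Fgf10, Fgf15 (−2.51 ± 0.31) and Fgf21 (−1.95 ± 0.24) fell (Fisher's exact test adjusted p = 0.0204, camera 0.195). The median of that group was 0.09, so it did not fall as a whole. Of 3 metallothionein genes Mt1 rose (camera adjusted p = 0.359). As the groups were picked from these libraries, their tests are not independent evidence.

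In the weighing that follows, the tests of sex and of cycling cells, the gradient test of each list, the test of higher genes under 5 CPM and the tests against the predicted rise were chosen only after the results were seen. The first pattern is the set of genes called between genotypes, since 2 of the 3 knockouts are female and both controls male. If sex were the cause, the male knockout would return to the controls, undoing the change seen in the female knockouts (a share of −1). Among 1280 autosomal genes called without knockout 3, that library went beyond the female knockouts by a median share of 0.11 (interquartile range −0.158 to 0.382). This argues against sex as the main cause of the calls, but not against a difference peculiar to the 2 controls, with which every knockout was compared. Knockout 3 is the 1 male knockout and also scored highest on the first principal component (61.3), so a partial return to the controls could be masked. Differences between single cultures or animals stay open, since the labels do not describe them. A gradient of library quality along the first principal component was not tested for these genes, and the component separated the genotypes.

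The second pattern is the joint fall of amino acid response and glycolysis genes (36 called members). In the male libraries alone (2 controls and knockout 3) their median was −0.857 (−1.04 to −0.729). They were called with knockout 3 included, so the direction there was fixed. Over all 24 members of each list, knockout 3 minus controls had a median of −0.855 (amino acid) and −0.713 (glycolysis). The female knockouts minus controls had −0.988 and −0.701. These list medians argue against sex as the whole cause, as far as 1 male knockout library can. For library quality along the first principal component, the amino acid list had slopes within controls and knockouts of −0.105 and −0.311 of the slope between groups. Its median thus did not fall along the component within either group, which argues against such a gradient only as far as 2 libraries per slope can. The slopes came from controls 1 and 2 and from knockouts 1 and 3, which differ in sex. The component was also drawn from the same genes and separated the genotypes, so it is no independent measure of quality. For the glycolysis list (0.165 and 0.352) quality cannot be told apart from genotype, since the share within knockouts lies between the bounds. Fewer cycling cells are argued against by the cell cycle genes, with a median of −0.0365 (−0.148 to 0.0798). Loss of Jag1, doxycycline if the controls did not receive it, and a difference in oxygen, cell density or medium use between cultures stay open. They were not tested apart.

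The third pattern is the rise of weakly expressed genes, hair cell genes among them. Olfactory and vomeronasal receptor genes, taken as a measure of background reads, had a median of 0.703 over 742 tested genes, of which 16 rose, and 244 with the sex term (camera adjusted p = 4.97e-21; adjusted p = 0.377 with an estimated correlation). The 138 higher genes under 5 CPM rose by a median 3.19 times the rise predicted from that background (1.85 to 6.86), and 38 of them by under 2 times, so background and a real rise cannot be told apart for them (24 passed when tested against the predicted rise). The 201 higher genes of at least 5 CPM rose by a median 13.1 times that predicted (6.67 to 31.2). That ratio cannot decide, since a call there was estimated to need a median ratio of 9.78 (lowest 2.09). Tested against the predicted rise, 142 of the 201 passed, with a median of 0.704 beyond it (0.534 to 0.863). Over all 201 the median beyond it was 0.644 (0.488 to 0.794). This argues against background as their whole cause, though they were picked as higher from the same libraries. The 59 that no longer passed went from 0.736 (0.541 to 0.854) to 0.546 (0.392 to 0.647). For the hair cell list neither background nor sex can be excluded. Percentile 99.2 among expression-matched random lists lies between the bounds set in advance. The observed rise was a median 0.665 of that predicted, and against the predicted rise 1 of 29 members passed. The list's median beyond the predicted rise was −0.221, beside −0.23 for the receptor genes. Rasd2 rose 14.2 and Pou4f3 2.27 times as predicted (ratios of 8.56, 6.45 and 6.23 for Jag2, Espn and Hes6, which were not called). The median of 0.582 in the male libraries rests on knockout 3, which had the most receptor reads (4090 CPM).

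Otoa and Oc90 were picked after seeing the values. Otoa, the gene of a protein that anchors the tectorial membrane, stood at 27.5 and 15.9 CPM in the controls and 149, 85.3 and 81.1 CPM in the knockouts (log2 fold change 2.27, adjusted p = 0.0662). Oc90, an otoconial protein gene, stood at 1.03 and 61.0 CPM in the controls and 1.12, 1.02 and 0.574 CPM in the knockouts (adjusted p = 0.195). The model with a sex term called 14 genes for sex, 8 of them on X or Y. Among 3253 tested transcripts that did not match the annotation, edgeR called 0, with 454 at an unadjusted p under 0.05 and a median log2 fold change of 0.41.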
